A study of Synechocystis sp. PCC 6803 with 10 samples.

How the data were processed

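Total RNA from 10 samples of Synechocystis was labelled directly with Cy3, 2 µg per array and without a cDNA step per the labels. It was read on 1-colour Agilent arrays, 1 array per sample. The labels do not say whether the 0 h and 24 h samples of a strain came from the same cultures. Cells grew at 30 °C and 40 µmol photons per m2 and s. The strain with the PsrR1 plasmid (PsrR1+) and the strain with the empty plasmid (control) were sampled at 0 h (2 arrays each) and at 24 h (3 arrays each) of copper depletion, and the labels call the arrays of a group biological replicates. Per the file headers, the scanner values are spot intensity values made with Feature Extraction 10.7.3.1, background-subtracted and spatially detrended but not scaled between arrays. Other columns hold, per the file headers, 0 or 1 flags per spot (unit: other). The deposited value table holds log2 values: each column followed the log2 of the median spot signal of its own array (r from 0.9994 to 1.0), and each column had the same median of 11.32. The deposited log2 values were quantile-normalized by the authors without a visible background subtraction. The submitters' processing notes name limma without a version.

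The array holds 42303 spots, of which 1417 are controls, with 20363 probes of 45 to 60 nt for 8830 feature names. No more than 1 probe reads 4011 of the features, and 415 probe sequences appear under more than 1 name. For the main results log2 processed signal was taken per spot, the 75th percentile of the array was subtracted, spots were averaged per probe and kept probes per feature. Outlier spots were left out unless no probe of the feature would then have been read on every array, which kept them for 96 probes. A probe was kept where at least 50% of its spots were well above background on every array of at least 1 group, which left 8148 features and removed 682. A dim probe can thus pass through the group where it is brightest, so the filter can favour probes that differ between groups. The processed signal at the 75th percentile ran from 2892 to 4638 per array and was 2.11 to 3.44 times the net signal of the negative controls, lowest in control replicate 3 at 24 h. On arrays of slide 1, the control arrays at 24 h, 0.643% to 0.665% of spots were outliers, against at most 0.029% on the others. Within groups the arrays correlated from 0.966 to 0.995.

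A linear model with 1 coefficient per group over the 4 groups was fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with empirical Bayes moderation (6 residual and 3.44 prior degrees of freedom). The 5 contrasts were strain at 24 h, strain at 0 h, time in each strain, and their interaction. A feature was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Where the lower group was not well above background, the fold is given as a lower bound against the background limit. The 16 gene lists (photosystem I, photosystem II, phycobilisome, tetrapyrrole and chlorophyll, cytochrome b6f and electron carriers, ATP synthase, NDH-1, carbon fixation and uptake, copper response, ribosomal proteins, heat shock and proteolysis, high light, nitrogen, iron, phosphate, and PsrR1 targets) held 253 entries, of which 248 were measured. They were tested with camera at a preset correlation of 0.01 among the 3332 coding features, with camera at an estimated correlation and with fry, adjusted over the 16 lists. The lists, the contrasts, the named genes and the alternatives were fixed before the data were examined. Named by that rule were 9 fixed genes (psaL, psaJ, psaF, chlN, cpcA, psbB, petJ and petE, and PsrR1 itself) in each comparison, the coding features with the largest called rises and falls without overlap between the arrays of the groups (10 each at 24 h, 5 each in the other comparisons, the interaction without the overlap rule), the 4 largest such rises and falls of noncoding and antisense RNAs at 24 h, and up to 4 members with the smallest p of each list described.

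The level of PsrR1 was planned but is not given, since 0 feature names hold PsrR1 or SyR1. Genome positions are not given in the sources used here, because the annotation table held 0 locus tags of the array's style; gene symbols come from the lists. Slide as a block could not be fitted, because each 24 h group lay alone on its slide. The labels do not say whether the replicate numbers pair the arrays. Over 13 pairs of arrays with the same number, the correlation of deviations from the group mean ran from -0.644 to 0.65, with 4 above 0.1 and 9 below -0.1. The 4 lay within a strain between 0 h and 24 h (0.258 to 0.65) and the 9 between strains (-0.644 to -0.148). Each time comparison had 2 such pairs, too few to decide, so the main fit stayed unpaired.

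The procedure was tested on simulated data. With values drawn for each feature from its mean and estimated spread, it recovered 26.9%, 95.5% and 98.5% of features changed 1.5-fold, 2-fold and 4-fold at 24 h with 5.8% false calls, and 10.4%, 68.7% and 98.5% at 0 h with 4.1% false calls. The draws were independent between features, with 1 spread for all groups and no slide difference. In the data the median SD was 0.23 in the control strain at 24 h and 0.12 in each other group, so these rates need not hold there. Alternatives planned beforehand were normexp background correction (offset 50), quantile normalization, median centring, no filter on dim probes, the median of probes, outlier spots kept, the deposited values, an intensity trend with a robust prior, a fit of the compared arrays alone, the replicate number as a block, and leaving out each array. Array weights, a block with crossed replicate numbers at 0 h, and a block of replicate numbers within each strain for the comparisons over time, were added after the data were seen. The REML estimate of the weights stopped before it converged, so gene-by-gene weights replaced it after its counts had been seen. Overlaps of called features were tested with Fisher's exact test, medians of sets were bounded with 2000 bootstrap draws at 95%, and sets matched on mean signal in 20 bins were drawn 1000 times. Both kinds of draw take features, not arrays, so these intervals do not measure the spread between samples.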

Results

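RNA levels were measured in the cyanobacterium Synechocystis in a strain that carries a self-replicating plasmid with the small RNA PsrR1 under the petJ promoter, called the PsrR1+ strain here, and in a control strain with the empty plasmid. The petJ promoter is repressed by copper, so that removing copper from the medium releases it. Cells were sampled before copper removal (0 h, n = 2 samples per strain) and 24 h after it (n = 3 per strain), 10 arrays in all. Total RNA was labelled directly with 1 dye and each sample was read on 1 array with 40886 spots that are not controls. The 8148 tested features are coding genes, 5' leaders, antisense RNAs, internal and other noncoding transcripts. The share of spots well above background ran from 75.4% (control, 24 h, replicate 3) to 91.0% (PsrR1+, 0 h, replicate 1). The median SD between replicates was 0.23 log2 units in the control strain at 24 h, against 0.12 in each of the other 3 groups. Arrays of the 0 h groups shared slide 3, the PsrR1+ arrays at 24 h lay on slide 2 and the control arrays at 24 h on slide 1, so that at 24 h the strain and the slide could not be told apart. The 0 h arrays were scanned on another day than the 24 h arrays, and no culture was kept with copper for 24 h. Copper removal, time in culture, slide and scan day could therefore not be told apart in the comparisons of 0 h and 24 h. The number of arrays limits the precision. Levels are log2 signals relative to the array's 75th percentile, and positions in the genome are not given in the sources used here.

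The response of the copper-regulated electron carriers shows the state of the cells. In the control strain petJ (sll1796), which codes for cytochrome c6, rose by a log2 fold change of 3.15 (SE 0.20, n = 3 against 2) within 24 h, and petE (sll0199), which codes for plastocyanin, the copper protein that cytochrome c6 replaces, fell by 2.00 (SE 0.17). In the PsrR1+ strain petJ rose by 1.96 (SE 0.20) and petE fell by 2.93 (SE 0.17). The limma adjusted p was 0.000131 and 0.000876 in the control strain and 0.0013 and 6.62e-05 in the PsrR1+ strain, with no overlap between the arrays of 0 h and 24 h. At 0 h the strains lay close together, with differences of 0.01 for petJ and -0.02 for petE (adjusted p = 1.0 for each). At 24 h both transcripts were lower in the PsrR1+ strain, petJ by a log2 fold change of -1.18 (SE 0.18, adjusted p = 0.00442; 0.34 ± 0.20 against 1.52 ± 0.35, SD, n = 3) and petE by -0.95 (SE 0.16, adjusted p = 0.00627; 1.36 ± 0.20 against 2.31 ± 0.27). No feature on the array is named PsrR1 or SyR1, so the level of the overexpressed RNA itself was not analysed here.

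**Figure D1:**
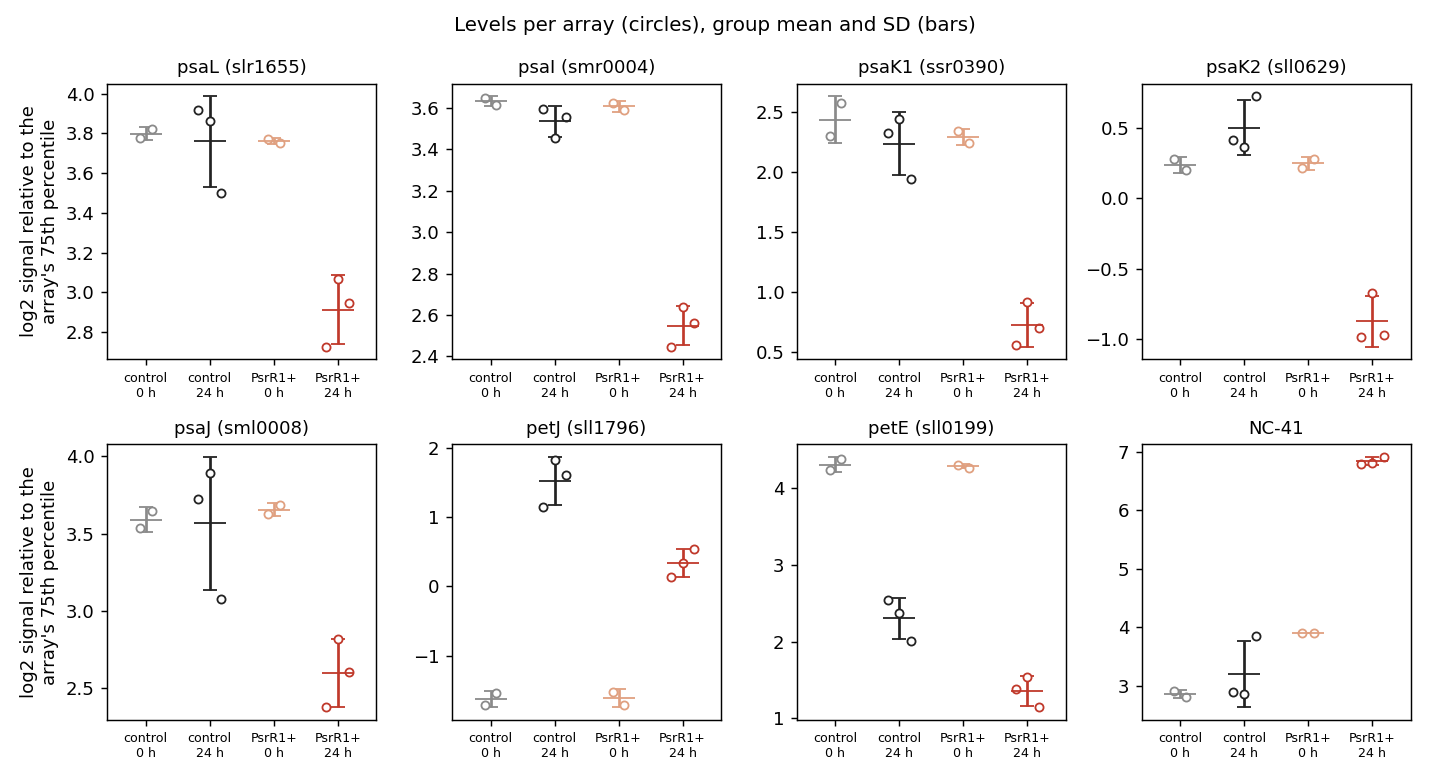
Log2 signal relative to the array's 75th percentile (vertical axis) for each array (circles) in the 4 groups (horizontal axis), with the group mean and SD as bars, n = 2 at 0 h and n = 3 at 24 h. The petJ level lay near -1.62 in each strain at 0 h and reached 1.52 in the control strain and 0.34 in the PsrR1+ strain at 24 h.

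The comparison of the strains at 24 h addresses which transcripts change when PsrR1 is overexpressed. Several genes for small subunits of photosystem I were lower in the PsrR1+ strain. The gene psaL (slr1655), whose product takes part in forming photosystem I trimers, had a level of 2.91 ± 0.17 against 3.76 ± 0.23 (SD, n = 3), a log2 fold change of -0.85 (SE 0.14, adjusted p = 0.00634), negative in all 4 of its probes. The genes psaK1 (ssr0390) and psaK2 (sll0629) fell by 1.51 (SE 0.16, adjusted p = 0.00056) and 1.38 (SE 0.14, adjusted p = 0.000394). The gene psaI (smr0004, 1 probe) fell by 0.99 (SE 0.10, adjusted p = 0.000465) and psaM (smr0005) by 0.48 (adjusted p = 0.0339). The gene psaJ (sml0008) fell by 0.97 (SE 0.20, adjusted p = 0.0198). The psaJ call was lost with another background correction (adjusted p = 0.151), with the deposited values (0.073) and in a fit of the 6 arrays alone (0.0644). It was also lost without PsrR1+ replicate 1 (0.0706), PsrR1+ replicate 3 (0.0709) or control replicate 1 (0.0651) at 24 h. The genes of the large core subunits and of psaD did not pass the test, with log2 fold changes of 0.38 for psaA (slr1834), 0.50 for psaB (slr1835) and 0.47 for psaD (slr0737). In all, 6 of the 12 measured photosystem I genes were lower and 0 higher (6 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.52. Camera's adjusted p for the list was 1.85e-06 with its preset correlation, and the list was no longer called with an estimated correlation (adjusted p = 0.401). Fry, which asks whether the genes of a list move one way on balance, gave 0.012. Among the 9 wrong splits of the 6 arrays into 3 and 3, camera called this list in 4 (adjusted p = 1.55e-06, 1.09e-05, 0.00719 and 0.0323). In each of these the group with 2 PsrR1+ arrays was the lower one.

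Of the 6 genes listed here as PsrR1 targets, 2 were lower and 0 higher over all features and 2 were lower adjusted over the list alone: psaL and psaJ. Both also count among the lower photosystem I genes, so the calls of these 2 lists are not separate results. The target list was recalled from knowledge of the study and could not be checked here. Its genes may have been chosen in part on these samples, so it is not independent evidence of a direction. The others did not pass the test: psaF (sll0819) had a log2 fold change of -0.56 (SE 0.23, adjusted p = 0.145), chlN (slr0750) of -0.66 (SE 0.31, adjusted p = 0.197), cpcA (sll1578, 1 probe) of 0.24 (SE 0.18, adjusted p = 0.419) and psbB (slr0906) of 0.19 (SE 0.20, adjusted p = 0.546). The list had a median of -0.61 and a camera adjusted p of 0.00994, which was lost with an estimated correlation (adjusted p = 0.636) and without control replicate 2 at 24 h (0.132). Fry gave 0.401. Without control replicate 3 at 24 h, the array with the weakest signal over background, psaF (-0.86, adjusted p = 0.00762) and chlN (-1.09, adjusted p = 0.0068) were called as well. Without that array cpcA had a log2 fold change of 0.024 and psbB of -0.064, and the list had a median of -0.92 (camera adjusted p = 6.19e-07).

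Across all features at 24 h, 257 were higher and 493 lower in the PsrR1+ strain (limma, adjusted p below 0.05), 750 of the 8148 tested. Among the coding genes 96 rose and 65 fell, of which 10 and 18 by at least 2-fold. The falls by size were led by sll0630 with a log2 fold change of -2.21 (SE 0.26, adjusted p = 0.000903; -2.32 ± 0.40 against -0.11 ± 0.47, SD, n = 3) and sll0678 (1 probe) with -2.04. They went on with ssr2016, a homologue of the plant protein PGR5 of cyclic electron flow, with -1.90, hliB (ssr2595), which codes for a high-light-inducible protein, with -1.81, ssr2194 with -1.64 and copM (sll0788), which codes for a periplasmic copper-binding protein, with -1.57. The genes psaK1 and psaK2 followed, together with slr0944 with -1.44 and slr1544 with -1.35. The largest rises were those of sll1174 (2.12), sll0140 (1.96), sll1642 (1.82), slr1485 (1.69), sll0983 (1.68), sll0982 (1.52), ssr2802 (1.47), sll1439 (1.44), sll0060 (1.13) and slr1857 (1.01), the last of which codes for a glycogen debranching enzyme. In the control strain sll1174 and sll0060 were not well above background, so they were at least 3.86-fold and at least 1.44-fold higher. In the control strain sll0140 was well above background on 1 of the 3 arrays, and slr0944 in each strain on 2 of the 3. The probe of sll1642 is also listed under an internal transcript of the same gene. Of the 10 named rises 7 rested on 1 probe and 6 were not called without the filter on dim probes, and of the 10 named falls 2 (sll0678 and slr0944). Without that filter, which adds their dim probes, the log2 fold change was 0.15 for sll1174, 0.03 for slr1485, 0.25 for sll1642, 0.33 for sll1439, 0.37 for sll0060 and 0.49 for ssr2802, and -0.83 for sll0678 and -0.77 for slr0944. The folds of these 8 genes, bounds included, therefore hold for the kept probes alone. The filter can keep a probe through the group where it is brightest, so it can favour probes that differ between the strains. The genes sll0982 and sll0983, with 4 probes each, kept their calls without the filter. With another background correction ssr2016 (-1.07, adjusted p = 0.0696), slr0944 (-0.50, 0.361), slr1485 (0.87, 0.0591) and sll0060 (0.24, 0.78) were not called. For slr1857 the call was also lost with the median of its probes (adjusted p = 0.0587), in a fit of the 6 arrays alone (0.0595), and without PsrR1+ replicate 2 (0.0685) or 3 (0.0772) at 24 h.

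All 750 called features had no overlap between the arrays of the strains, which chance gives to 10% of unselected features. A call already picks features with a large difference for their spread, so this is no separate evidence. The count fell to 418, 316 and 322 without PsrR1+ replicate 1, 2 and 3 at 24 h and to 441 without control replicate 1, and rose to 1542 without control replicate 2. It was 351 with another background correction, 369 in a fit of the 6 arrays alone, and 560 with the replicate number as a block.

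Among the called noncoding and antisense RNAs at 24 h more were lower than higher in the PsrR1+ strain. Of the 545 noncoding RNAs 6 were higher and 78 lower, and of the 1511 antisense RNAs 64 and 118. The noncoding RNA NC-41 had the largest rise among them, to 6.84 ± 0.07 from 3.20 ± 0.57 in the control strain (SD, n = 3), a log2 fold change of 3.63 (SE 0.23, adjusted p = 9.77e-05) that both of its probes shared. In the PsrR1+ strain NC-41 rose by 2.93 (adjusted p = 0.000662) between 0 h and 24 h, while in the control strain the difference was 0.34 (adjusted p = 0.501). At 0 h it differed between the strains by 1.04 (adjusted p = 0.37). The sources used here do not say which RNA NC-41 is, nor whether its probes read the overexpressed PsrR1 itself. Next came the antisense RNAs sll1672-as6 (2.20), slr1946-as1 (1.69, at least 2.26-fold higher) and slr1039-as2 (1.64). The noncoding RNA NC-1443 was at least 6.25-fold lower in the PsrR1+ strain, where it was not well above background (fitted log2 fold change -3.77, adjusted p = 0.000163). The antisense RNAs sll1906-as1 and sll0877-as3 fell by 2.41 and 2.34, and NC-1248 by 2.19. NC-1248 was well above background on 1 of the 3 PsrR1+ arrays and 2 of the 3 control arrays, and sll1672-as6 on 1 of the 3 control arrays, so the sizes of these 2 changes are uncertain. Each of these except NC-41 was read by 1 probe, and NC-1248 and slr1946-as1 lost their calls with another background correction, with the deposited values, in a fit of the 6 arrays alone and without single arrays. The slr1946-as1 call was also lost with quantile normalization (adjusted p = 0.0581).

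Among the other gene lists at 24 h, the 9 ATP synthase genes had positive log2 fold changes without exception, with a median of 0.69 and 0.78 for atpD (sll1325), yet 0 were called over all features and 7 were higher adjusted over the list alone. Camera's adjusted p was 0.00994, lost with an estimated correlation (adjusted p = 0.663), and fry gave 0.327. Without control replicate 3 at 24 h the median was 0.39 and atpD 0.50, and without control replicate 2 they were 0.87 and 1.02, with atpD called (adjusted p = 0.0148). Of the 10 copper-response genes 3 were lower (petE, petJ and copM; 4 lower and 1 higher adjusted over the list alone), with a median of -0.22 and a camera adjusted p of 0.019. The call was lost with an estimated correlation (adjusted p = 0.401), the median of probes (0.078), the deposited values (0.146) and without control replicate 2 at 24 h (0.0568). Fry gave 0.000457. Of the 19 genes of carbon fixation and uptake 0 were called in either way of adjusting, with a median of -0.11, -0.63 for ccmL (sll1030) and a camera adjusted p of 0.0104. This call was lost with an estimated correlation (adjusted p = 0.636), with the deposited values (0.136) and without control replicate 2 at 24 h (0.179), and fry gave 0.694. Left-out arrays moved the median from -0.27 (without control replicate 3 at 24 h, where ccmL was called with -0.83) to -0.02 (without PsrR1+ replicate 3 at 24 h).

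The remaining lists were not called by camera. Of 28 photosystem II genes 4 were lower (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.249). The gene psbZ (sll1281) fell by 0.67, psbL (smr0007) by 0.60, psbJ (smr0008) by 0.58 and psbF (smr0006) by 0.46. Each was a call that some of the other settings and left-out arrays ended. Of 13 genes of cytochrome b6f and the electron carriers 2 were lower (petJ and petE) and 1 higher (2 and 2 adjusted over the list alone; camera adjusted p = 0.827). The higher one, petB (slr0342) with 0.84 (adjusted p = 0.049), was not called without any 1 of 8 of the 10 arrays. Its call was also lost in 5 of 10 other settings (limma, adjusted p up to 0.113). In each of 4 lists 1 gene was lower. These were ndhD2 (slr1291, -0.68) of 18 NDH-1 genes (camera adjusted p = 0.33) and hspA (sll1514, -0.96), which codes for a small heat shock protein, of 19 heat shock and proteolysis genes (0.302). They were also hliB of 12 high-light genes (0.246; 2 lower adjusted over the list alone) and isiA (sll0247, -0.93), which codes for the iron-stress chlorophyll protein, of 10 iron genes (0.682). The calls of ndhD2, hspA and isiA were lost in some settings and without single arrays. No gene was called among 38 ribosomal protein genes (median 0.30, camera adjusted p = 0.0604), 15 phycobilisome genes (0.24, 0.249), 23 tetrapyrrole and chlorophyll genes (0.04, 0.302), 15 nitrogen genes (0.40, 0.827) and 9 phosphate genes (-0.01, 0.249), in either way of adjusting. For the lists of photosystem II, tetrapyrrole, NDH-1, heat shock, high light and iron the median was positive while camera's direction was down.

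**Figure D2:**
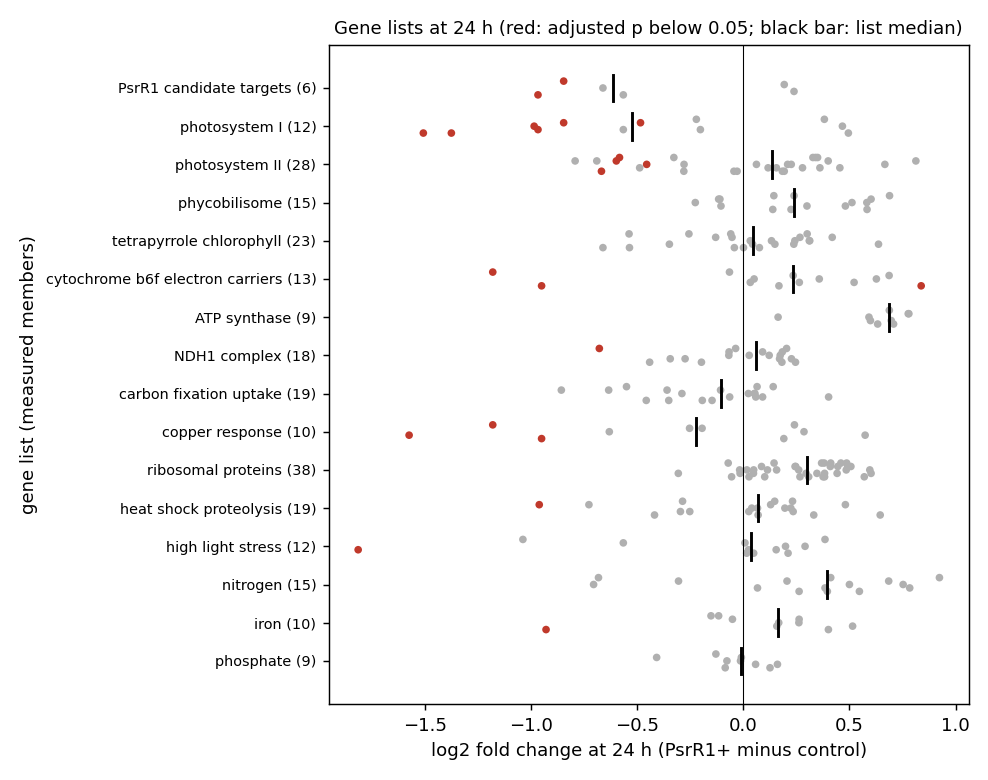
Log2 fold change at 24 h, PsrR1+ minus control strain (horizontal axis), of each measured member of the 16 gene lists (vertical axis, number of members in parentheses), red where the adjusted p was below 0.05, with the list median as a black bar. The photosystem I list had a median of -0.52 and the ATP synthase list of 0.69.

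The strains already differed at 0 h, before copper removal, in a comparison that lay within 1 slide. All 9 coding genes called were lower in the PsrR1+ strain, led by ssr2194 with a log2 fold change of -2.37 (SE 0.28, adjusted p = 0.00752; -1.80 ± 0.01 against 0.57 ± 0.05, SD, n = 2), ssr2016 with -2.33 (adjusted p = 0.017), hliB with -2.0 (adjusted p = 0.0151), slr1544 with -1.90 (adjusted p = 0.0134) and hspA with -1.41 (adjusted p = 0.0437). In all, 58 features were lower and 2 higher (limma, adjusted p below 0.05), and 38 of the lower ones have names that start with Spacer, which the sources used here do not explain. The higher ones, named after their values were seen, were the 5' leader slr1897-5'UTR with 4.10 (adjusted p = 1.82e-06) and the antisense RNA slr1667-as1 with 1.49 (adjusted p = 0.0098). All 19 measured heat shock and proteolysis genes had negative log2 fold changes, with a median of -0.23 and 1 lower gene (hspA) in either way of adjusting. Camera's adjusted p was 6.59e-08, lost with an estimated correlation (adjusted p = 0.265), and fry gave 0.985. The other 15 lists were not called by camera or fry at 0 h. The psaL difference was -0.04 (adjusted p = 1.0). The arrays of the strains did not overlap for any called feature, which chance gives to 33.3% of unselected features with 2 arrays against 2. As at 24 h, a call picks for this, so it is no separate evidence. The count of 60 fell to 15, 19, 38 and 10 without PsrR1+ replicate 1 or 2 or control replicate 1 or 2 at 0 h and to 39 without PsrR1+ replicate 3 at 24 h. The genes ssr2194, ssr2016, hliB and slr1544 were not called without PsrR1+ replicate 1 or 2 or control replicate 2 at 0 h, and hspA lost its call without any 1 of 8 of the 10 arrays. The call of ssr2016 was also lost with another background correction (-0.83, adjusted p = 0.433), with the deposited values (0.0817), in a fit of the 4 arrays alone (0.158) and with the replicate number as a block (0.0575). In the fit of 4 arrays hliB and slr1544 were not called (0.107 each) nor was hspA (0.067), which was lost in 4 more settings (adjusted p up to 0.11). The gene ssr2194 lost its call only where single arrays were left out. The count was 14 in a fit of the 4 arrays alone and 36 with the replicate number as a block.

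Features lower at 0 h were for the most part lower at 24 h too: 54 were lower at both times, and the 2 higher ones were higher at both. Chance would give 3.51 lower at both (Fisher's exact test, two-sided, p = 3.29e-62). The 2 comparisons share no array, but they share 1 estimate of the spread per feature. A feature with a small estimate is more easily called in both. The features, 38 of the 54 being Spacer features, are not independent either, so this p-value can overstate the overlap. The coding genes ssr2016, ssr2194, hliB, slr1544, hspA, sll0528 and slr7076 were among the 54, with log2 fold changes at 24 h from -0.95 for sll0528 to -1.90 for ssr2016. Across all features, which are not independent replicates, the changes at the times had a Pearson r of 0.329 and a Spearman rho of 0.065.

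**Figure D3:**
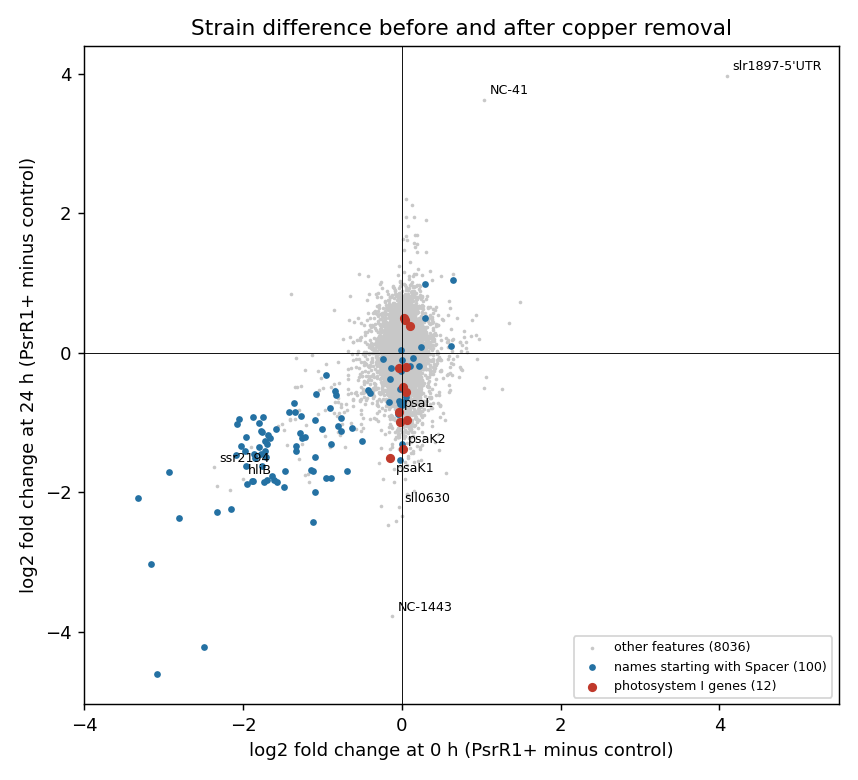
Log2 fold change between the strains (PsrR1+ minus control) at 0 h (horizontal axis) and at 24 h (vertical axis), 1 point per feature, with Spacer features in blue and photosystem I genes in red. The 12 photosystem I genes lay near 0 at 0 h and spread from 0.50 to -1.51 at 24 h, while 38 Spacer features were called lower at 0 h and 69 at 24 h.

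The control strain between 0 h and 24 h covers the time of copper removal without the PsrR1 gene on the plasmid, but no test here separates copper removal from time in culture, slide or scan day. Besides petJ, the rises were led by slr1452 with a log2 fold change of 3.67 (SE 0.41, adjusted p = 0.00434; -1.44 ± 0.42 at n = 3 against -5.11 ± 0.04 at n = 2, SD), slr1453 with 3.43 and slr1454 with 2.47, all genes of sulfate uptake, and ssr2439 with 2.51. After petE, the largest falls were sll0383 with -1.84 (adjusted p = 0.000876), sll0384 with -1.64, slr0732 with -1.58 and sll1174, at least 2.14-fold lower at 24 h, when it was not well above background. The calls of sll0384, slr0732 and sll1174 were lost with another background correction and without either control array at 0 h, and the sll1174 value turned to 0.43 (adjusted p = 0.315) without the filter on dim probes. The 9 phosphate genes had positive log2 fold changes with a median of 0.45. The gene pstS1 (sll0680), which codes for a phosphate-binding protein, was called with 0.77 (adjusted p = 0.0387), 5 were higher adjusted over the list alone, and camera's adjusted p was 2.22e-07 (0.0189 with an estimated correlation; 0.00314 with fry). The call of pstS1 alone was lost without any 1 of 8 of the 10 arrays. The other 15 lists were not called by camera or fry. In all, 89 features rose and 80 fell (limma, adjusted p below 0.05), a 47.3% share of falls that was 25.8% with quantile normalization, 33.0% with median centring and 26.8% with the deposited values. The count of 169 was 12 and 10 without control replicate 1 and 2 at 0 h, where slr1452, slr1453, slr1454 and ssr2439 were not called. It was 69 and 285 without control replicate 1 and 2 at 24 h, 110 without either PsrR1+ array at 0 h, and 86 and 75 without PsrR1+ replicate 2 and 3 at 24 h. It was 52 with another background correction, 23 in a fit of the 5 arrays alone and 28 with the replicate number as a block, but 286 with a block within each strain.

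In the PsrR1+ strain between 0 h and 24 h, falls outnumbered rises. After petE, the largest falls were those of ndhR (sll1594), which codes for a regulator of carbon uptake genes, with a log2 fold change of -2.42 (SE 0.52, adjusted p = 0.0299), copM with -2.36 (SE 0.24, adjusted p = 0.00117), slr7032, at least 2.89-fold lower, and sll0783 with -2.20. The rises were led by slr0601 with 2.58 (adjusted p = 0.000217), slr1452 with 2.49, slr1453 with 2.35, petJ with 1.96 and ssr2439 with 1.48. The calls of slr1452 (0.57), slr1453 (0.44), ssr2439 (0.57), slr7032 (-1.07) and sll0783 (-1.26) were lost with another background correction, which gave the values in parentheses, and without PsrR1+ replicate 1 at 0 h. Without the filter on dim probes slr7032 had -0.89 (adjusted p = 0.0787). The genes psaL (-0.85, adjusted p = 0.0174), psaJ (-1.05, adjusted p = 0.0299), psaI (-1.06), psaK1 (-1.56), psaK2 (-1.12) and psaM (-0.75) fell, 6 of the 12 photosystem I genes (7 adjusted over the list alone), and ndhD2 fell by 2.06 (adjusted p = 0.000667). Camera called the lists of photosystem I (adjusted p = 8e-05), PsrR1 targets (0.00181), NDH-1 (0.00181; 4 lower, 6 adjusted over the list alone) and carbon fixation and uptake (0.00115; 2 lower in either way) as lower. It called phosphate as higher (0.00115; 0 genes called, 1 adjusted over the list alone). With an estimated correlation the adjusted p was 0.145 for phosphate and 0.59 for each of the other 4. Fry called photosystem I, phosphate and, among the 11 lists that camera did not call, copper response (adjusted p = 0.0124 each; 3 copper-response genes higher and 3 lower). In all, 152 features rose and 338 fell (limma, adjusted p below 0.05), a 69.0% share of falls that was 52.2% with quantile normalization, 56.9% with median centring and 48.1% with the deposited values. The count of 490 was 46 and 206 without PsrR1+ replicate 1 and 2 at 0 h and 217, 185 and 163 without PsrR1+ replicate 1, 2 and 3 at 24 h. It was 316 without either control array at 0 h, and 318, 782 and 1075 without control replicate 1, 2 and 3 at 24 h. The gene psaL was not called without PsrR1+ replicate 1 (adjusted p = 0.165) or 2 (0.0789) at 0 h or PsrR1+ replicate 1 (0.054) or 3 (0.059) at 24 h, and ndhR and psaJ without any 1 of the 5 PsrR1+ arrays. With the replicate number as a block psaL (0.0537), ndhR (0.0511) and psaJ (0.0573) were not called, nor was psaJ with another background correction (0.0754). The psaK2 call was lost without PsrR1+ replicate 1 at 0 h (0.0587), and the psaM call without either PsrR1+ array at 0 h (0.118 and 0.0825) or PsrR1+ replicate 3 at 24 h (0.0568). The count was 192 with another background correction, 1031 in a fit of the 5 arrays alone and 259 with the replicate number as a block, but 1348 with a block within each strain.

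The changes over time in the strains overlapped: 35 features rose in both and 40 fell in both, against 1.66 and 3.32 expected by chance, and 3 went opposite ways (Fisher's exact test, two-sided, p = 1.49e-38 for rises and 1.28e-34 for falls). The features are not independent, and both comparisons use the same estimate of the spread per feature, so these p-values can overstate the overlap. A slide or scan-day difference between 0 h and 24 h would give the same agreement, so the overlap does not single out copper removal. Features that rose in both strains included petJ, slr1452, slr1453 and ssr2439, and petE fell in both.

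The interaction of strain and time tests whether the change over 24 h differed between the strains. It includes the strain difference at 24 h, where each strain lay alone on its slide, so a slide difference would enter it in full. The coding genes called for the interaction were sll1642 (log2 difference of 1.75, SE 0.24, adjusted p = 0.0313), sll0983 (1.63, SE 0.24, adjusted p = 0.032) and sll0982 (1.35, SE 0.18, adjusted p = 0.0313), whose change was higher in the PsrR1+ strain. The change was lower for psaK2 (-1.39, SE 0.21, adjusted p = 0.0366), slr1025 (-1.20, SE 0.15, adjusted p = 0.0313) and psaI (-0.96, SE 0.16, adjusted p = 0.0481). The genes psaL (-0.81, adjusted p = 0.206), psaJ (-1.03, adjusted p = 0.285), petJ (-1.19, adjusted p = 0.143) and petE (-0.93, adjusted p = 0.191) did not pass this test, though psaJ did without control replicate 3 at 24 h (-1.27, adjusted p = 0.0464). In all, 7 features had a higher and 21 a lower change (limma, adjusted p below 0.05), 11 of them antisense RNAs. Camera called the lists of photosystem I (adjusted p = 3.61e-08; 2 genes lower, 6 adjusted over the list alone), PsrR1 targets, ATP synthase, and carbon fixation and uptake (0.0023 each), copper response (0.0148) and ribosomal proteins (0.0239). No gene of the last 5 lists was called over all features, and 2 PsrR1 targets and 3 copper-response genes were lower adjusted over the list alone. With an estimated correlation the adjusted p was 0.263 for photosystem I and copper response, 0.574 for PsrR1 targets and carbon, 0.662 for ATP synthase and 0.781 for ribosomal proteins. Fry called copper response alone (adjusted p = 0.0228). The count of 28 was 0 without any 1 of 8 arrays (each PsrR1+ array, the control arrays at 0 h and control replicate 1 at 24 h) and 60 and 50 without control replicate 2 and 3 at 24 h. It was 4 with a block of replicate numbers within each strain. It was 0 without the filter on dim probes, where sll1642 had 0.19 and slr1025 -0.35, and with the replicate number as a block (limma; 952 and 804 features at an unadjusted p below 0.05). It was 9 with another background correction, with a 55.6% share of lower changes against 75%, and 79 with the deposited values.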

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

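The tests of slide and the splits of the arrays for gene lists were chosen only after the results they bear on were seen.

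The change over 24 h differed between the strains, by a test of the interaction, for 28 features (limma, adjusted p below 0.05). That test includes the strain difference at 24 h, where each strain lay alone on its slide. A slide difference would enter it in full and cannot be told apart from a strain difference here. Among the coding genes the log2 difference, PsrR1+ change minus control change, was 1.75 for sll1642, 1.63 for sll0983, 1.35 for sll0982, -1.39 for psaK2 (sll0629), -1.20 for slr1025 and -0.96 for psaI (smr0004). Among the named noncoding and antisense RNAs it was 2.60 for NC-41 (which RNA this feature reads, and whether that is PsrR1, is not given in the sources used here), -3.65 for NC-1443 and -2.33 for sll1906-as1. The size for NC-1443 is uncertain, since it was not well above background in the PsrR1+ strain at 24 h. In the same test camera called the lists of photosystem I (adjusted p = 3.61e-08), PsrR1 targets (0.0023), ATP synthase (0.0023), carbon fixation and uptake (0.0023), copper response (0.0148) and ribosomal proteins (0.0239), with a preset correlation only. Leaving out any 1 of 8 arrays (each PsrR1+ array, the control arrays at 0 h and control replicate 1 at 24 h) took the count of features to 0, and leaving out control replicate 2 or 3 at 24 h took it to 60 and 50. The count was also 0 without the filter on dim probes and with the replicate number as a block, and 4 with a block of replicate numbers within each strain, of which 2 were among the 28, so the genes named here rest on the unpaired fit of all arrays.

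The 750 features called between the strains at 24 h were set against noise and slide. Only the real split of the 6 arrays into 3 and 3 gave as many features (1 of 10 splits, the highest other count being 0), and with 10 splits the share cannot go under 0.1. For the 5 gene lists called by camera, 5 of the 10 splits gave as many, the highest other count being 11, so those calls also arise between mixed groups of these arrays, each of which keeps part of the strain difference. Without control replicate 3, the array with the weakest signal over background, the count was 673, of which 561 were among the 750. Those 561 calls did not need that array. Leaving it out also changes the shared estimate of the spread. The count for the PsrR1+ strain over time, which does not use that array, went from 490 to 1075. The total of 673 therefore cannot tell whether that array was a source of the other calls. The slide stays open, since 0 slides hold both strains at 24 h, and the strain difference that the design names cannot be told apart from it.

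The 54 features lower in the PsrR1+ strain at both times, 38 of them Spacer features, were set against slide, plasmid copies and low signal. The 95% intervals given for them come from draws of features, which are not independent, and hold no spread between samples. Slide alone is argued against, since 58 features were called lower at 0 h with both strains on 1 slide, and these, picked by their difference at 0 h, had a median log2 fold change of -1.43 at 24 h (95% interval -1.63 to -1.31; -0.99 for the 20 that are not Spacer features), against -0.027 in features matched on signal, though a slide share in its size stays open. Fewer copies of the plasmid pSYSA are argued against at 0 h: the 102 pSYSA coding features had a median log2 fold change there of -0.012 (95% interval -0.06 to 0.03), against -1.23 for the Spacer features. At 24 h the pSYSA median was -0.17, against 0.11 for the chromosomal coding features and -1.16 for the Spacer features. A small share of plasmid copies at 24 h therefore stays open. A shift shared by features of like signal is argued against. The median was 0.019 (95% interval -0.01 to 0.05) in 54 features matched on signal, against -1.62 in the 54 themselves. These were picked for being lower at 0 h, so the test cannot tell whether noise at low signal helped to pick them. The 100 measured Spacer features had a median level of 1.29, against -1.48 for the chromosomal coding features, so as a set they were not dim. These features were called lower already at 0 h, before copper removal. What lies behind that, such as a difference between the cultures or clones, was not tested, and other causes stay open.

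The lower photosystem I transcripts at 24 h were set against signal, scaling and slide. High signal is argued against: of 1000 random coding lists matched on signal, none had a median as low as -0.52. The matched median was 0.12 (95% interval -0.17 to 0.36). With the real list counted in, the share is 0.1%, the smallest these draws can give. The draws took genes singly, while the list's genes had an estimated correlation of 0.386. This share can therefore overstate how rare such a list is. Scaling is argued against only for the list's place below the other coding genes. The highest camera adjusted p was 0.000238 over 4 other ways to scale or background-correct the arrays, all with the preset correlation. With an estimated one the list was not called (adjusted p = 0.401). Camera sets the list against the other coding genes, so a shift shared by all genes of an array would not show in it. The list was also called in 4 wrong splits of the 6 arrays (adjusted p = 1.09e-05, 1.55e-06, 0.00719 and 0.0323), each time lower in the group with 2 PsrR1+ arrays, which keeps part of the strain difference. The slide stays open, since 0 slides hold both strains at 24 h, and an effect of PsrR1 cannot be told apart from it.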

How the results depend on the processing

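Array weights, the crossed replicate block and the within-strain replicate block were chosen only after the data were seen. Of the 84 calls on named features, 30 kept direction and call under every planned setting and left-out array. Of these, 20 were differences between the strains at 24 h, among them psaL, psaK1, psaK2, psaI, petJ, petE, copM, hliB, sll0630, sll0982, sll0983 and NC-41. Signal over background leaves only bounds for features not well above background in a group. Normexp background correction ended 31 and leaving out the filter on dim probes 19 of the calls on named features, and no test tied these losses to low signal. Normexp also moved the median of all features from 0.02 to 0.16 at 0 h, from -0.07 to 0.04 in the control strain over time, from -0.09 to -0.21 in the PsrR1+ strain over time and from -0.01 to -0.25 for the interaction. A slide block was not run, since it could not be fitted.

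The 750 features called at 24 h became 351 with normexp, 369 with only the arrays compared and 1395 with array weights. Left-out arrays took it from 316 (without PsrR1+ replicate 2 at 24 h) to 1542 (without control replicate 2 at 24 h). There were 418, 322 and 441 without PsrR1+ replicate 1 and 3 and control replicate 1 at 24 h. The 60 at 0 h became 14 with only the arrays compared, 36 with the replicate block and 101 with the crossed block, which was added because the same-numbered 0 h arrays correlated at -0.644. Left-out arrays took it from 10 (without control replicate 2 at 0 h) to 69 (without control replicate 3 at 24 h). The 169 of the control strain over time became 52 with normexp, 23 with only the arrays compared, 28 with the replicate block, 286 with the within-strain block and 267 with array weights. Left-out arrays took it from 10 (without control replicate 2 at 0 h) to 285 (without control replicate 2 at 24 h). The 490 of the PsrR1+ strain over time became 192, 1031, 259, 1348 and 1488 in these settings. Left-out arrays took it from 46 (without PsrR1+ replicate 1 at 0 h) to 1075 (without control replicate 3 at 24 h). The 28 of the interaction became 9 with normexp, 0 without the filter on dim probes and with the replicate block (952 and 804 at an unadjusted p below 0.05, limma). It became 4 with the within-strain block, 79 with the deposited values, 52 with a trend and robust prior and 82 with array weights. Left-out arrays took it from 0 (without any 1 of 8 arrays) to 60. The 5 gene lists became 0 with an estimated correlation and 2 with fry, and ranged from 3 (without control replicate 2 at 24 h) to 7. Fewer arrays leave fewer degrees of freedom and a different estimate of the spread; beyond that, the cause was not tested.

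Where a lone array was left in a group at 0 h, it was assumed to vary like the other groups. The sll1174 fall in the control strain, called before, turned to 0.43 without the filter on dim probes, which added probes near background. The other values that changed sign had not been called, and the cause was not tested. At 24 h, phoA (sll0654) turned to -0.12 with normexp, -0.27 without the filter and -0.042 with the deposited values, and sigD (sll2012) to 0.019 with the median of probes. At 0 h, normexp gave -0.059 for psaF, -0.007 for cpcA, 0.22 for chlN, -0.026 for psbB and -0.023 for psaJ. Quantile normalization and the deposited values gave 0.009 and 0.022 for petE and 0.001 and 0.002 for psaL. In the control strain over time, chlN was 0.10 with normexp, 0.042 with the deposited values and 0.015 with the replicate block. There psaL was 0.027 with median centring and 0.019 with the block, and psaJ was 0.032 with quantile normalization, 0.042 with median centring and 0.096 with the block. In the PsrR1+ strain over time pstA (sll0682) was -0.045 with normexp. Left-out arrays gave, at 0 h, -0.094 to 0.047 for petE, -0.029 to 0.20 for cpcA, -0.081 to 0.10 for petJ and -0.23 to 0.027 for chlN. In the control strain over time they gave -0.43 to 0.026 for psaF, -0.53 to 0.16 for chlN, -0.12 to 0.092 for psaL and -0.19 to 0.22 for psaJ. They gave -0.064 to 0.33 for psbB at 24 h, and for the interaction -0.064 to 0.31 for cpcA and -0.15 to 0.24 for psbB.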

Other observations

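The features of this part were chosen after their values were seen, and no explanation is offered for them here. In the control strain the clock genes kaiA (slr0756), kaiB (slr0757) and kaiC (slr0758) fell by 0.84, 0.79 and 0.77 on the log2 scale over 24 h (limma, adjusted p = 0.0231, 0.0157 and 0.0477, n = 3 against 2). In the PsrR1+ strain kaiA fell by 0.61 (adjusted p = 0.0422) and kaiB by 0.62 (0.0233), and kaiC had a log2 fold change of -0.32 (0.288). The genes with neighbouring locus tags sll0381, sll0382 and sll0385 fell in the control strain by 1.14, 1.12 and 1.14, next to sll0383 and sll0384. The genes slr1728 and slr1729 of a potassium-transporting ATPase rose by 1.48 and 1.64 in the control strain (adjusted p = 0.0141 and 0.0137) and by 1.01 and 1.29 in the PsrR1+ strain (0.0299 and 0.0177). The interaction for slr1728 and slr1729 had an adjusted p of 0.595 and 0.699.

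The 5' leader slr1897-5'UTR was higher in the PsrR1+ strain by a log2 fold change of 4.10 at 0 h and 3.97 at 24 h (adjusted p = 1.82e-06 and 3.66e-07), with levels of 2.19 ± 0.11 against -1.91 ± 0.14 at 0 h (SD, n = 2) and 1.81 ± 0.12 against -2.16 ± 0.13 at 24 h (SD, n = 3). Over time it had a log2 fold change of -0.38 in the PsrR1+ strain (adjusted p = 0.133) and -0.25 in the control strain (adjusted p = 0.331).

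Of the 100 measured Spacer features, 38 were lower and 0 higher in the PsrR1+ strain at 0 h (median log2 fold change -1.23), and 69 were lower and 2 higher at 24 h (median -1.16). Their names carry a second number. Where it is 0, 1 of 27 was lower at 0 h and 11 at 24 h. With the second number 1, 15 of 41 were lower at 0 h and 29 at 24 h, and with 2, 22 of 32 and 29. Between 0 h and 24 h the median in the control strain was 0.08, 0.21 and 0.13 for the second number 0, 1 and 2, and in the PsrR1+ strain -0.21, 0.64 and -0.08. Among the 102 coding features of the plasmid pSYSA 9 were lower and 2 higher at 24 h, with a median of -0.17 (95% interval -0.23 to -0.08). Among the 3221 chromosomal coding features 56 were lower and 94 higher, with a median of 0.11 (95% interval 0.10 to 0.12).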
